A study of Cupriavidus necator H16 with 3 samples.

How the data were processed

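Total RNA of 3 samples of Cupriavidus necator H16 was extracted with TRIzol, and stranded libraries were made with a VAHTS mRNA-seq kit, per the labels' protocols. The submitters' processing notes name FastQC, Trimmomatic, Bowtie2 and featureCounts; their versions, the genome build and the settings for strand and for reads that match several places are not given in the sources used here. The authors deposited, per the file headers, TPM for each of the 3 libraries, which is a read count divided by gene length and scaled so that each library sums to 1 fixed total. They also deposited log2 TPM values for each library, per the file headers. These equalled log2 of the TPM without a pseudocount to within 5.0e-09, and were blank where the TPM was 0. Only the TPM columns entered the tests; the authors' mean and standard error columns were not used. Each library summed to 1000000 or 999999 TPM.

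The design had been written for counts. Because the unit was TPM, the tests written for that case were used, and alternatives that need counts or gene lengths could not be run. TPM hold no depth, so no counting error or detection floor could be computed. A repeated library was looked for only by counting the tested genes with exactly equal deposited TPM, and the likeness of libraries was described by correlations and by the SD of log2 values in place of a biological coefficient of variation. Abundance is relative: a transcript that takes a larger part of a library lowers the TPM of the others.

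Genes were identified by the locus tags, names and annotations of the deposited table. The reference table given for this species was of another strain, N-1, whose locus tags do not match, so it was not used and no coordinates are given. Genes with the prefix H16_A were taken as chromosome 1, H16_B as chromosome 2 and PHG as the megaplasmid pHG1. The table listed 15 rRNA genes, at 19.1 TPM in total on average, and 58 tRNA genes, at 14154 TPM; these were left out of the tests. Of the other 6626 genes, 293 had a mean under 1 TPM and were not tested, and 51 genes were listed at 0 in every library.

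The level of a gene was log2(TPM + 1) minus the median of that quantity over the tested genes of the same library. Differences and ratios are on this scale, which understates those of genes with low TPM. Levels were tested against a 2-fold threshold with limma 3.58.1 in R 4.3.3 (treat with an abundance trend and robust moderation, a single mean for the group, two-sided), with Benjamini-Hochberg adjustment over all tested genes at 0.05. For lists also the adjustment over the list alone was computed. Lists were tested by their median level in each library, averaged over the 3 libraries, against the medians of the same list moved by each of 6333 steps along the gene order of the replicons. This exact two-sided circular-shift test keeps neighbouring genes together; its smallest p is 0.000316. P-values were adjusted over the 28 lists with at least 3 tested members, and separately over the 3 replicons. Pairs of genes or operons were compared by the log2 ratio of their mean log2(TPM + 1) within each library, with mean, SD and an exact sign-flip permutation test whose smallest p is 0.25. A pair was said to differ where its mean was over 2 SD. This rule describes the 3 libraries and sets no error rate.

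The 30 gene lists, the pairs and the rule for named genes were fixed before the data were examined, as were the tests and most alternatives. The lists cover the Calvin cycle, hydrogenases and their maturation, PHB, nitrogen, oxidative stress, metals, respiration, central metabolism, translation, protein quality control, motility, pili, secretion, DNA repair, phosphate, stationary phase and mobile elements. They were matched by symbol, locus tag or words of the annotation, which gave 809 matches. Of these, 42 were left out because their annotated product has another function; this was done by annotation, after some values had been seen, whereas the design had foreseen it only for genes matched by locus tag. The genes that make up each pair were likewise identified from the annotation once the table was at hand. The text names the 20 genes with the highest mean TPM, some of the 2 highest and the lowest members of each list by mean TPM and of the members of the pairs, picked for brevity after their values were seen, and the 10 genes with a mean of at least 10 TPM whose variance was highest against limma's trend. The last criterion replaced one written for counts. Others are said to be chosen after their values were seen. In the analysis Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3.

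The steps were tested on simulated data. With 200 of 6333 genes set to known levels, the gene test recovered 77.6%, 95.5% and 100.0% of those at 1.5, 2.0 and 3.0 log2 units from the median. It called 0.620% of the genes inside the 2-fold band. The SDs were dealt out to genes at random here, so any link of spread to abundance was not kept. Of 100 random lists made of runs of neighbours, 6.0% had a shift-test p under 0.05, and 86.0% did so after 4.0 log2 units had been added. The first of these shares lies near 0.05 by construction, because lists at random places were ranked against all shifts of the same list. The second holds for that size, layout and added level, and gives no power for the lists tested below. The alternatives were the mean as reference level, pseudocounts of 0.1 and 5, no filter, a fold threshold of 4, list means, rRNA and tRNA kept in, and leaving out each replicate in turn. Requiring 1 TPM in every library, quantile normalisation, random lists of the same size not matched on length (10000 draws, or 1000 for replicons), the median of gene means as the list value, keeping all list matches, and ratios to single copies of the bo3 and bd oxidases and of katE were added after seeing the data.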

Results

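The data are transcript abundances of Cupriavidus necator H16, a soil bacterium that grows on H2 and CO2 and stores carbon as poly(3-hydroxybutyrate) (PHB). The wild type strain (DSM 428) had grown for 36 h at 30 °C without an organic substrate, in minimal medium with little nitrogen, under a gas phase of 74% H2, 13% CO2 and 13% O2 at 0.23 MPa. The cultures held 0.8 g/L of ZnO nanosheets, a piezocatalyst (a solid that drives redox reactions when mechanically strained), and were shaken on a tilting agitator at 200 rpm. All 3 libraries, replicates 1 to 3, belong to this 1 group, so no contrast with another condition was made: the comparisons are between genes within these libraries and between the libraries. Nothing in the labels says that the replicates came from separate cultures, so the spread between these 3 samples may be technical. The p-values of limma and of the sign-flip test rest on that spread alone. Those of the circular-shift tests compare places along the gene order and do not measure it. The values are TPM, read counts divided by gene length and scaled to 1 fixed total per library, which keep no read depth, so the depth of each library is unknown. Of 6699 genes listed, 6626 were neither rRNA nor tRNA, and 6333 of those had a mean of at least 1 TPM and were tested.

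By the mean of the 3 libraries, the most abundant transcript was that of H16_B1672, a helix-turn-helix protein of the XRE family, at 21139 ± 4492 TPM (SD, n = 3). It was followed by H16_B1650, annotated as hypothetical, at 12909 TPM on average but with 953, 15284 and 22491 TPM in replicates 1, 2 and 3 (8118 without replicate 3), by the D-amino-acid dehydrogenase gene dadA1 (H16_A0817) at 11657 ± 2697 TPM and by H16_B1929, a cold shock protein, at 11162 ± 1622 TPM. H16_A0386, annotated as a modulator of sigma 54, stood at 9056 ± 1632.8 TPM, the porin H16_A3402 at 8832 ± 3040 TPM and a further cold shock protein, H16_B2205, at 8311 ± 2968 TPM. Among the 20 most abundant genes were also phaB1 (H16_A1439, acetoacetyl-CoA reductase of PHB synthesis) at 4709 ± 818 TPM, rseA (negative regulator of an envelope stress sigma factor) at 4347 ± 604 TPM, and a pair of copper genes, cueR (H16_A3667) and copP2 (H16_A3668), that differed widely between libraries. The remaining members were the unnamed or hypothetical genes PHG294, H16_A2313, H16_A0148, H16_B0701, H16_A1136 and H16_A0946, the fimbriae-associated H16_B0181, the outer membrane protein H16_A0788 and the ribosomal protein gene rpmF. These 20 genes took 14.5% ± 1.11 of the TPM outside rRNA and tRNA (SD, n = 3). Against the median gene of the same library, 1836 genes were more than 2-fold above and 2020 more than 2-fold below, and 2477 passed neither way. The test was limma against a 2-fold threshold, Benjamini-Hochberg adjusted over all tested genes. In the counts of genes that follow, above and below mean that a gene passed this test. The order of the 2 most abundant genes turned without replicate 1, with 18887 TPM for H16_B1650 and 18795 TPM for H16_B1672. Behind H16_B1672, dadA1 took the place of H16_B1650 without replicate 2, at 13155 TPM. Without replicate 3, H16_B1929 took that place, at 10746 TPM. Members named as highest in a list are ranked by the same mean, and leaving out 1 library changed the first member of the lists for membrane-bound hydrogenase, maturation, nitrogen, oxidative stress, terminal oxidases, ATP synthase, denitrification and stringent response. Without replicate 3, H16_B1650 and cueR no longer passed (adjusted p = 0.205 and 0.155 in limma), and copP2 was lost without replicate 3 (adjusted p = 0.412) and without replicate 2 (adjusted p = 0.081).

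Genes of the 3 replicons differed in level. The median gene of chromosome 1 lay 0.67 log2 units above the library median, with 1341 of 3548 tested genes above and 746 below. The median gene of chromosome 2 lay at -1.20 log2 units, with 355 of 2390 genes above and 1132 below. Both differed from sets of the same size shifted along the joined gene order (exact circular-shift test on the library average, two-sided, adjusted p = 0.0327 for each). Many of these shifted sets overlap the replicon itself. Chromosome 2 also holds most of the genes outside chromosome 1, so these results are not independent of each other. The medians had these directions in 3 of 3 libraries. The megaplasmid pHG1, which carries the hydrogenases and one copy of the CO2 fixation operon, was split, with 140 of 395 tested genes above and 142 below, and its median of 0.09 log2 units did not stand apart (exact adjusted p = 0.998). Chromosome 1 held 66.3% ± 0.558 of the TPM outside rRNA and tRNA, chromosome 2 held 23.9% ± 1.42 and pHG1 held 9.84% ± 1.30 (SD, n = 3).

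The genes for growth on H2 and CO2 were among the most abundant lists. In the Calvin cycle list, 25 of 26 tested members were above the median and 1 was below. The list median of 4.43 log2 units exceeded chance (exact circular-shift test over 28 lists, two-sided, adjusted p = 0.0144). The list counts 12 genes of the cbb operon once on pHG1 and once on chromosome 2. Reads may have been shared between these near-identical copies. The copies are then not independent, and the count and the p-value may overstate how far the list stood out. The epimerase genes cbbE2 and cbbEp were highest, at 1924 ± 377 and 1473 ± 167 TPM. The large subunit of RuBisCO, the CO2-fixing enzyme, stood at 1217 ± 421 TPM for cbbL2 on chromosome 2 and 836 ± 347.1 TPM for cbbLp on pHG1. The activator gene cbbR was the only member below, at 8.40 ± 1.91 TPM. All 6 tested members of the soluble hydrogenase list, the enzyme that reduces NAD with H2, were above, led by hoxW at 2074 ± 458 TPM and hoxH at 1651 ± 458 TPM (list median 4.97, exact adjusted p = 0.00737). All 4 members of the list of regulatory hydrogenase and hox regulator genes were above, with hoxB at 1979 ± 461 TPM and hoxA at 996 ± 65.5 TPM (median 4.73, exact adjusted p = 0.0442). That call was lost without replicate 1 (exact adjusted p = 0.0548) and with the list mean in place of the median (0.0522). Of the 17 maturation genes 11 were above and 1 was below, with hypA2 at 1551 ± 320 TPM and hypF1 at 1543 ± 75.8 TPM (median 4.03, exact adjusted p = 0.00531; list mean 2.955). The member below was hypA3 at 10.2 ± 7.33 TPM (6.005 without replicate 1), whose call was lost without replicate 2 (adjusted p = 0.12 in limma) and without replicate 3 (0.0853). All 11 members of the membrane-bound hydrogenase list were above, from hoxR at 776 ± 131 TPM to hoxK at 188 ± 65.1 TPM, but the list median of 3.02 was not past the threshold (exact adjusted p = 0.153). Adjusted over the list alone, the numbers of genes above and below equalled those over all genes tested in every list with a tested member except 5, which are given with their lists.

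**Figure D1:**
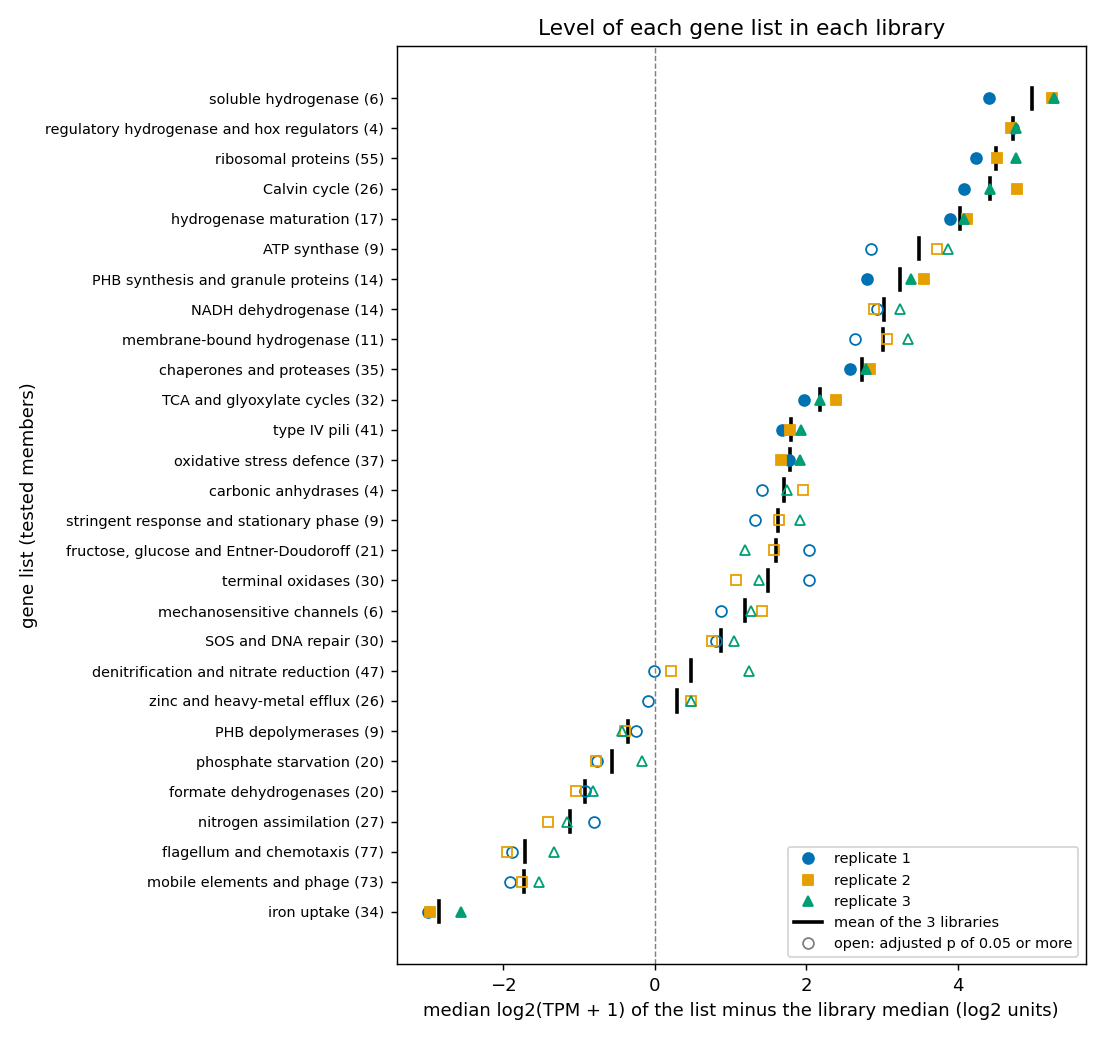
Level of 28 gene lists, with the number of tested members in brackets. The horizontal axis is the list's median log2(TPM + 1) minus the median of the tested genes of that library; points are the 3 libraries, black bars their mean, and open points mark lists with an adjusted p of 0.05 or more. The soluble hydrogenase list is highest at 4.97 and the iron uptake list lowest at -2.85.

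Genes of the membrane-bound hydrogenase lay below those of the soluble and the regulatory one. The structural genes of the soluble enzyme (hoxF, hoxU, hoxY, hoxH) exceeded those of the membrane-bound enzyme (hoxK, hoxG) by 2.44 ± 0.61 log2 units, a ratio of 5.42 (SD, n = 3). The membrane-bound enzyme's genes lay below those of the regulatory hydrogenase (hoxB, hoxC), with a log2 ratio of -2.70 ± 0.19. Each difference was more than 2 SD and had the same direction in 3 of 3 libraries. With 3 libraries, an exact sign-flip permutation test cannot give a p below 0.25, and this holds for each of the 18 pairs compared. The pHG1 copy of the cbb operon lay below the chromosome 2 copy by a log2 ratio of -0.42 ± 0.04 over its 12 genes, with -0.58 ± 0.17 for cbbL and -0.89 ± 0.17 for cbbS. These copies are near-identical and the authors' counting could have split reads between them, so the levels of single copies are uncertain. Within RuBisCO, cbbS transcripts lay below cbbL transcripts by a log2 ratio of -0.54 ± 0.22.

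Genes of PHB synthesis were abundant and those of its breakdown were mostly not. Of 14 tested members of the synthesis and granule list, 10 were above the median and none was below (list median 3.24, exact circular-shift test, adjusted p = 0.00531). After phaB1 the highest was phaP2, a phasin that coats the storage granule, at 3161 ± 1106 TPM. The synthase gene phaC1 stood at 723 ± 59.0 TPM and the thiolase gene phaA at 1010 ± 175 TPM. The depolymerase list had 2 of 9 members above and 3 below and did not stand apart from chance (median -0.36, exact adjusted p = 0.723). Its highest member, the oligomer hydrolase gene phaY2, stood at 276 ± 6.08 TPM. The other member above was phaZ1 at 113 ± 9.64 TPM, and the lowest was phaZ on pHG1 at 6.67 ± 1.18 TPM. The gene phaZ5 had 129, 270 and 24.8 TPM in replicates 1, 2 and 3, and passed as above only without replicate 3 (adjusted p = 0.0112 in limma). The call of phaY1 as below was lost without replicate 1 (adjusted p = 0.0651 in limma) and without replicate 2 (0.0922). The operon phaC1-phaA-phaB1 exceeded the mean of the 9 depolymerases, which hides these differences, by 5.28 ± 0.08 log2 units (SD, n = 3). The paralogs were lower: phaC1 exceeded phaC2 by 3.56 ± 1.18 log2 units, and phaB1 exceeded phaB2 by 6.62 ± 1.45 and phaB3 by 7.52 ± 1.70 log2 units. Without replicate 3 the first ratio was 4.24 and the second 7.46, and the third was 6.56 without replicate 1 and 8.19 without replicate 2. The phasin phaP1, at 413 ± 111 TPM, did not differ from the mean of the other phasins by 2 SD (log2 ratio -0.68 ± 0.66, with 2 of 3 libraries in that direction). Among the latter, phaP3 had 21.1, 1184.6 and 576 TPM in replicates 1, 2 and 3, and it passed as above the median only without replicate 1 (adjusted p = 0.000191 in limma).

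The genes of NADH dehydrogenase and ATP synthase were above the median, but no respiration list passed as a whole. All 14 genes of NADH dehydrogenase, the respiratory complex I, were above the median (list median 3.02, exact circular-shift test, adjusted p = 0.145), led by nuoI at 1083 ± 152 TPM. All 9 genes of ATP synthase were above (median 3.48, exact adjusted p = 0.123), with atpC at 775 ± 116 TPM and atpG at 775 ± 105 TPM. Of 30 tested terminal oxidase genes 15 were above and 4 below (median 1.49, exact adjusted p = 0.145). The highest were ccoP of the cbb3 oxidase, a high-affinity oxidase used at low oxygen, at 914 ± 604 TPM (577 without replicate 3), and ccoG at 820 ± 389 TPM. The aa3 oxidase genes ctaC, ctaD and ctaE exceeded those of the bo3 quinol oxidases by 4.13 ± 0.14 log2 units and those of the bd quinol oxidases by 3.73 ± 0.15 log2 units (SD, n = 3). These means over copies hide wide differences between copies, by ratios chosen after the values were seen. The aa3 genes exceeded cyoABCD copies 1, 2 and 3 by 3.60 ± 0.59, 6.62 ± 0.24 and 2.17 ± 0.67 log2 units and cydAB copy 2 by 6.85 ± 0.05, but cydAB copy 1 (H16_B1176, H16_B1177) by only 0.61 ± 0.34, which is less than 2 SD. With a pseudocount of 5 the ratios to the means over copies were 3.52 and 2.94. Against the cbb3 oxidase the log2 ratio was -1.24 ± 1.01, with -0.42, -0.93 and -2.37 in replicates 1, 2 and 3, which is less than 2 SD. In the denitrification and nitrate reduction list, 16 of 47 tested members were above and 14 below (median 0.48, exact adjusted p = 0.719). The list median was -0.01, 0.21 and 1.24 in replicates 1, 2 and 3. The accessory genes nosD, with 1337, 1295 and 1523 TPM in the same libraries, and napE, at 1320 ± 364 TPM, were highest. The periplasmic nitrate reductase genes (nap) exceeded the membrane-bound ones (nar) by 5.73 ± 1.65 log2 units, or 4.82 with a pseudocount of 5, 4.83 without replicate 1 and 6.44 without replicate 3.

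**Figure D2:**
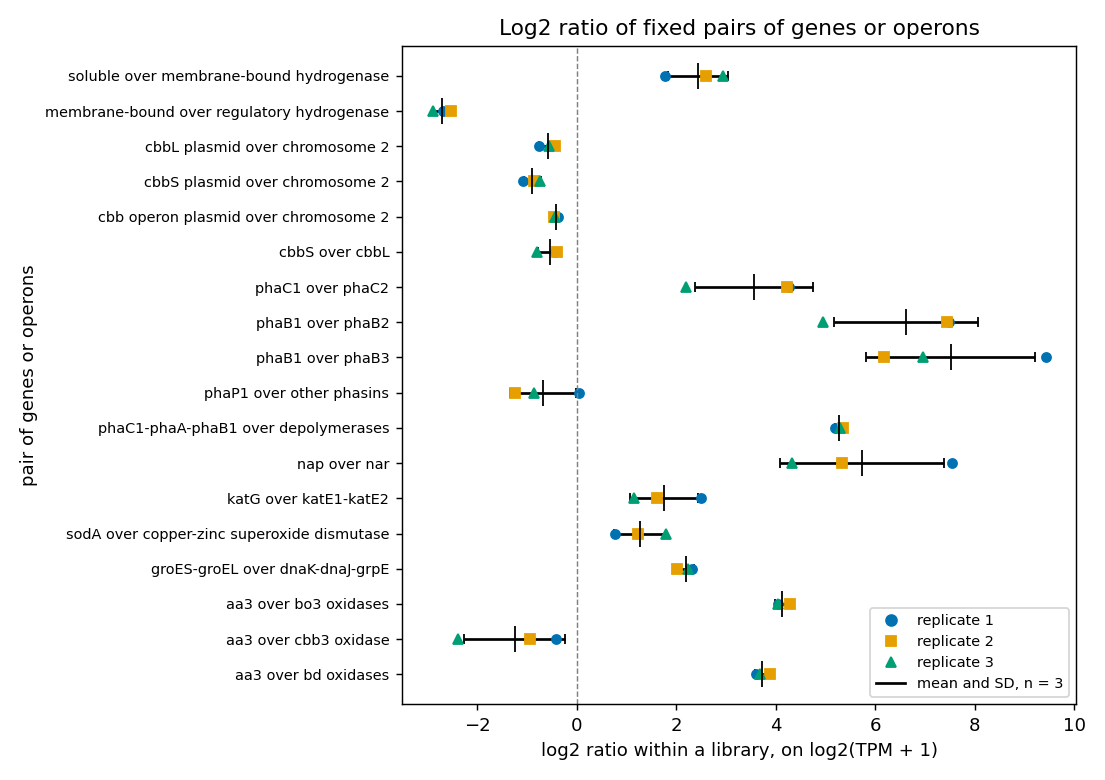
Log2 ratio of 18 fixed pairs of genes or operons within each library, on the log2(TPM + 1) scale. Coloured points are the 3 libraries, the vertical tick is the mean and the bar is the SD (n = 3). The ratio of phaB1 to phaB3 is highest at 7.52 and that of the membrane-bound to the regulatory hydrogenase lowest at -2.70.

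Lists for stress defence were above chance, and the metal lists were divided. In the oxidative stress defence list 21 of 37 members were above the median and 4 below (list median 1.79, exact circular-shift test, adjusted p = 0.00531). A thioredoxin, H16_A2394, stood at 1710 ± 135 TPM and a peroxiredoxin, H16_A1460, at 1662 ± 262.3 TPM. Catalases were lower, with katE1 at 140 ± 34.0 TPM, katG at 67.1 ± 25.6 TPM and katE2 at 1.70 ± 0.423 TPM. The log2 ratio of katG to the mean of katE1 and katE2 was 1.75 ± 0.68 (1.16 with a pseudocount of 5) and rests on the low katE2. Against katE1 alone, chosen after the values were seen, it was -1.09 ± 0.88, which is less than 2 SD. The superoxide dismutase gene sodA exceeded the copper-zinc superoxide dismutase gene H16_B1110 by 1.27 ± 0.52 log2 units. Of 35 chaperone and protease genes 27 were above and 2 below (median 2.73, exact adjusted p = 0.00442), with groEL at 3226 ± 444 TPM and groES at 2965 ± 246 TPM. The groES-groEL pair exceeded dnaK, dnaJ and grpE by 2.19 ± 0.16 log2 units (SD, n = 3). Of 26 tested genes for zinc and heavy-metal efflux 10 were above and 2 below, and the list did not stand apart (median 0.29, exact adjusted p = 0.723; list mean 1.13). Its highest members were the copper genes cueR and copA, at 4038 ± 2929 and 1968 ± 1427 TPM (copA 1145 without replicate 3), and the lowest was czcA2, of a cobalt-zinc-cadmium efflux system, at 1.39 ± 0.0643 TPM. The call of cueR was lost without replicate 3 (adjusted p = 0.155 in limma). No gene matched the zinc uptake list. The iron uptake list was the only one below chance, with 22 of 34 tested members below and 7 above, and 23 below when adjusted over the list alone (median -2.85, exact adjusted p = 0.0305). Its low members included the transporter H16_B1682 at 1.41 ± 0.606 TPM, whereas the bacterioferritin gene bfr2, for iron storage, stood at 1664 ± 263 TPM and the receptor PHG028 at 1296 ± 215 TPM. The iron call was lost when the list was summarised by its mean (-1.55, exact adjusted p = 0.121), and the median was -2.16 with a pseudocount of 5.

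Among the other lists, all 55 ribosomal protein genes were above the median (list median 4.51, exact circular-shift test, adjusted p = 0.00442, from the smallest p the shifts can give), led by rpmF at 4259 ± 463 TPM and rplM at 3029 ± 342.5 TPM. In the TCA and glyoxylate list 19 of 32 genes were above and 7 below (median 2.18, exact adjusted p = 0.00758; list mean 1.34), with isocitrate lyase iclB at 1233 ± 277 TPM; its p was 0.0522 (exact, adjusted) when summarised by the mean. In the type IV pili list 24 of 41 genes were above, or 25 adjusted over the list alone, and 9 below (median 1.80, exact adjusted p = 0.0442), with pilJ at 1035 ± 333 TPM. This call was lost without replicate 1 (exact adjusted p = 0.0548), without replicate 3 (0.0652), without the filter on low values (0.0638) and with the list mean (0.138). Nitrogen assimilation, in cultures short of nitrogen, had 10 of 27 genes above and 12 below, or 13 below adjusted over the list alone (median -1.13, exact adjusted p = 0.342). The median was 0.004 with the 4 matches left out for their annotation kept in, and -0.20 with the list mean. Its highest genes were those of glutamate synthase, gltB1 at 663 ± 235 TPM and gltD at 607 ± 406 TPM (387 without replicate 1). Flagellar and chemotaxis genes were mostly low, with 42 of 77 below and 8 above (median -1.72, exact adjusted p = 0.164; list mean -1.11), although the flagellar activator flhC1 stood at 772 ± 172 TPM and flagellin fliC at 612 ± 109 TPM. Mobile elements and phage genes had 44 of 73 below, or 45 adjusted over the list alone, and 10 above (median -1.73, exact adjusted p = 0.154), and tniB was highest at 541 ± 149 TPM.

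The remaining lists were not past the threshold either. The sugar list (fructose, glucose and the Entner-Doudoroff pathway) had 11 of 21 genes above and 3 below (median 1.60, exact adjusted p = 0.169; list mean 0.87), with pgl at 320 ± 52.1 TPM. Formate dehydrogenases had 3 of 20 above and 9 below (median -0.93, exact adjusted p = 0.539), with cbbB, next to the cbb operon of chromosome 2, at 544 ± 149 TPM. Carbonic anhydrases had 3 of 4 above and 1 below (median 1.71, exact adjusted p = 0.28; list mean 0.71), with caa at 162 ± 27.6 TPM and can2 at 4.73 ± 0.802 TPM. Mechanosensitive channels had 3 of 6 above and 1 below (median 1.18, exact adjusted p = 0.358), with mscL at 321 ± 15.4 TPM. SOS and DNA repair had 13 of 30 above and 6 below (median 0.87, exact adjusted p = 0.195), with lexA at 611 ± 79.6 TPM. Phosphate starvation had 6 of 20 below and none above (median -0.57, exact adjusted p = 0.713), with phoU at 61.0 ± 5.79 TPM. The stringent response and stationary phase list had 6 of 9 above, or 7 adjusted over the list alone, and none below (median 1.63, exact adjusted p = 0.189), with hfq at 854 ± 122 TPM and the sigma factor gene rpoS at 828 ± 149 TPM, and it passed when summarised by its mean (2.35, exact adjusted p = 0.0341). Type VI secretion had 2 tested members, vgrG at 4.71 ± 0.836 TPM and impE at 4.17 ± 0.355 TPM, too few for a list test.

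The 3 libraries ranked genes alike, but a small set of genes differed manyfold between them. Across the tested genes, which are not independent replicates, Pearson's r of log2(TPM + 1) was 0.978 between replicates 1 and 2, 0.959 between 1 and 3, and 0.977 between 2 and 3. The median SD of a gene between libraries was 0.25 log2 units, and 160 genes had an SD above 1. More than 2-fold differences were found for 299, 722 and 385 genes in the same pairs. No pair of libraries was identical, with 9, 1 and 3 of the tested genes at exactly the same deposited TPM. The genes with the largest spread for their abundance were the copper chaperone gene copZ (H16_A3669) with 42.3, 3429 and 5022 TPM in replicates 1, 2 and 3, and the copper efflux gene copF (H16_A2173) with 13.1, 816 and 679 TPM. They were followed by phaP3, by copP2 with 156, 4661 and 5978 TPM, by H16_A3605 with 33.6, 581 and 722 TPM, and by H16_B1650. PHG260, H16_A2188, the porin gene ompW2 and H16_B0793, a subunit of a TRAP transporter, completed the 10 most variable genes. The porin gene ompW2 had 108, 362 and 1793 TPM (mean 754, or 235 without replicate 3), and H16_B0793 had 845, 498 and 53.2 TPM (mean 465, or 276 without replicate 1). Without replicate 1, copZ, copF, phaP3, H16_A3605 and H16_A2188 passed as above the median, which they did not with all 3 libraries, and H16_B0793 no longer passed (adjusted p = 0.215 in limma). H16_B0793 was also lost without replicate 2 (adjusted p = 0.199 in limma), and ompW2 without replicate 2 (0.0982) and without replicate 3 (0.148). H16_B1650 and copP2 lost their calls as stated with the most abundant genes.

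**Figure D3:**
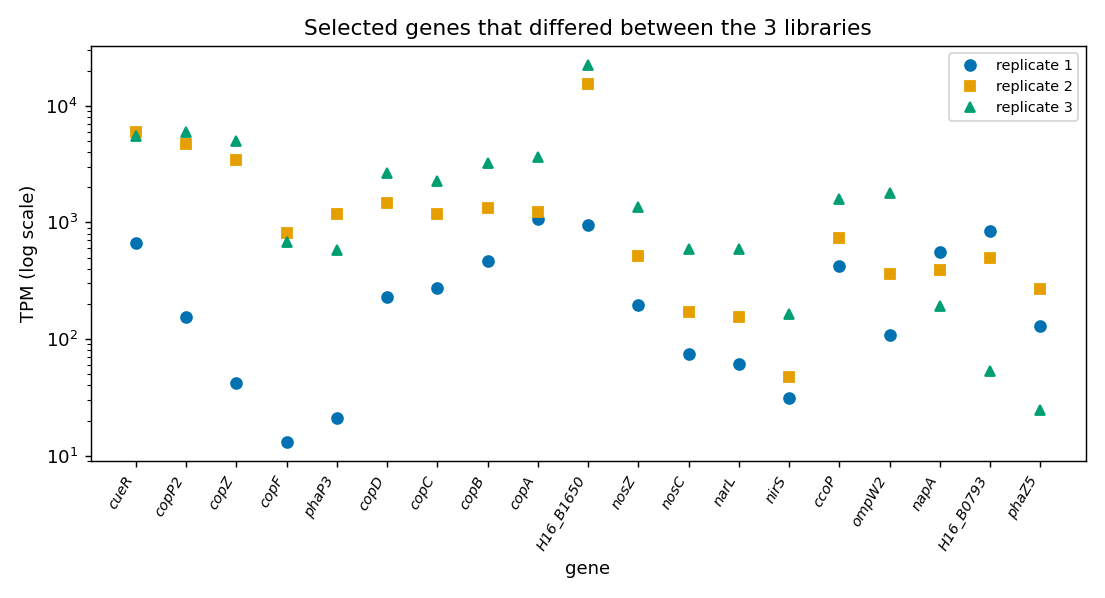
TPM of 19 genes in each library, on a log axis, with 1 point per library; the genes were chosen after their values were seen, as copper genes, genes of low-oxygen respiration and others with a large spread. The copper chaperone gene copZ runs from 42.3 TPM in replicate 1 to 5022 TPM in replicate 3.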

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

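Requiring 1 TPM in every library, quantile normalisation, random lists, the median of gene means as the list value, keeping all list matches, and single copies of oxidases and catalases in pairs were chosen after seeing the data; the other alternatives were planned. Gene counts stayed within 1.5 times under every alternative run except a fold threshold of 4, which left 1004 genes above and 1203 below. The spread between replicates, replicon medians and replicon shares kept their calls or moved by less than their spread. Random lists of the same size, which break up operons, gave 3 lists below chance and passed membrane-bound hydrogenase (3.02), NADH dehydrogenase (3.02), terminal oxidases (1.49), ATP synthase (3.48), the sugar list (1.60), flagellum and chemotaxis (-1.72) and mobile elements (-1.73), values in log2 units that are those of the main test; the changed chance distribution is the cause. With list means, 0 lists were below chance: regulatory hydrogenase (4.49), iron uptake (-1.55), TCA and glyoxylate (1.34) and type IV pili (1.24) were lost and the stringent response list (2.35) passed; without the filter, type IV pili (1.86) was lost; the cause was not tested. Leaving out each replicate in turn, regulatory hydrogenase ran from 4.71 to 4.74, lost without replicate 1, and type IV pili from 1.73 to 1.85, lost without replicate 1 and without replicate 3; the other lists kept their calls. Ratios moved by more than their SD with another pseudocount, which acts on genes near 0: aa3 over bo3 to 4.43 (pseudocount 0.1) and 3.52 (pseudocount 5), aa3 over bd to 4.20 and 2.94, and phaC1-phaA-phaB1 over depolymerases to 5.05 (pseudocount 5). Against single copies, aa3 over bo3 was 3.60, 6.62 and 2.17 (cyoABCD copies 1, 2 and 3), aa3 over bd was 0.61 and 6.85 (cydAB copies 1 and 2), and katG was 4.59 over katE2 but turned to -1.09 over katE1. Of the named genes, 5 were lost with other pseudocounts, and 10 were lost and 6 gained when a replicate was left out; no named gene or list that had passed changed direction, and of the pairs only katG over katE1 did. Keeping all list matches moved only nitrogen assimilation by more than 1.5-fold. Not run, since they need counts or gene lengths, were other scaling factors from counts, count-model tests, a minimum of 10 counts, values without length division and lists matched on length. Depth is unknown, so what it limits could not be computed. No paired analysis was possible because there is only 1 group.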

Other observations

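All tests and lists in this part were chosen after the data had been seen. Of 10 added lists matched by annotation, 8 passed the exact circular-shift test, which was not repeated under other settings. The lists were drawn up after levels had been seen, with H16_B1929, H16_B2205 and H16_A3402 already among the 20 most abundant genes. Their p-values, adjusted over these 10 lists alone, therefore describe the lists and are no independent support. All 6 cold shock genes were above the library median (list median 5.78, exact adjusted p = 0.00105), from H16_B1929 at 11162 ± 1622 TPM to H16_B2025 at 219 ± 77.9 TPM (SD, n = 3). Of 26 aminoacyl-tRNA synthetase genes 17 were above and 1 below (median 1.59, exact adjusted p = 0.0320), and of 13 translation elongation factor genes 10 were above and none below (median 2.38, exact adjusted p = 0.0174). Of 19 universal stress protein genes 9 were above and 2 below (median 1.67, exact adjusted p = 0.0411). Low lists included families for uptake and breakdown of organic substrates. Of 137 extra-cytoplasmic solute receptor genes, a large family of binding proteins in this genus, 88 were below and 5 above (median -2.09, exact adjusted p = 0.00105). Of 61 acyl-CoA dehydrogenase genes 34 were below and 13 above (median -1.70, exact adjusted p = 0.00947), and of 45 enoyl-CoA hydratase genes 24 were below and 8 above (median -1.53, exact adjusted p = 0.0114). Of 40 porin genes 25 were below and 6 above (median -2.00, exact adjusted p = 0.00105), although the porin H16_A3402 was among the most abundant transcripts. LysR-family regulators (median -0.28, exact adjusted p = 0.377) and TRAP transporters (median 0.13, exact adjusted p = 0.896) did not pass.

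The copper genes differed manyfold between libraries of the same group. The neighbours cueR, copP2 and copZ, which bind, sense or move copper, averaged 287, 4668 and 5513 TPM in replicates 1, 2 and 3, copDCBA 509, 1299 and 2938 TPM, and copF with its neighbours phaP3 and phaB3 13.4, 692 and 429 TPM. Of the 11 genes named for copper, 9 were lowest in replicate 1, where 39.1% of all tested genes were lowest, and copR and copS were lowest in replicate 2. This set was drawn up after 3 of its genes had been seen among the 10 most variable. Its median range was 3.22 log2 units. It was 0.41 for the 3496 other genes with a mean TPM between those of the lowest and highest copper gene, not matched further on abundance. This comparison is a description and cannot tell whether random variation of single genes is excluded. A single stretch of the genome deleted in 1 sample would act in 1 place, but genes with over 4-fold range lay in 4 separate places; an altered regulator, such as cueR, copR or copS, stays open. A mislabelled library stays open too. Replicate 1 differed more than 2-fold from replicate 2 in 299 genes and from replicate 3 in 722, and replicates 2 and 3 differed in 385. These counts do not single out replicate 1, but they cannot exclude mislabelling, since no other condition was at hand for comparison. Nothing in the labels shows that the libraries come from separate cultures, so a technical difference between them also stays open; no biological explanation was tested, and copper present in different amounts is a hypothesis that these data cannot test.

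A second difference ran through genes of the denitrification list. Of 47 tested genes of the denitrification list, fixed beforehand but singled out here after its values were seen, 36 were highest in replicate 3. Of all tested genes, 39.6% were highest there. The count passed the exact circular-shift test, run on the same count in each of 28 lists (adjusted p = 0.0155). This adjustment covers the choice of the list but not that of the count, which was devised after the values were seen. The result therefore describes the list and cannot decide whether random variation of single genes is excluded. The list was not alone in passing, since 56 of 77 flagellar and chemotaxis genes were also highest in replicate 3 (exact adjusted p = 0.00442). So were 35 of 55 ribosomal protein genes and 19 of 30 SOS and DNA repair genes, without passing (exact circular-shift test, adjusted p = 0.0906 and 0.0825). The nosRZCX genes averaged 224, 387 and 1033 TPM in replicates 1, 2 and 3, narX with narL 194, 246.7 and 862 TPM, and the nir genes 95.3, 76.5 and 185 TPM. The nap genes went the other way, with 608, 432 and 298 TPM, and nosLYFD, with 986, 898 and 1104 TPM, differed little. Outside this list, the cbb3 oxidase genes on chromosome 1, picked after their values were seen, averaged 333, 513 and 1149 TPM. Of the 30 terminal oxidase genes, however, 15 were highest in replicate 1 (exact circular-shift test, adjusted p = 0.594). The bd oxidase genes cydA1 (199, 140 and 157 TPM) and cydB1 (176, 122 and 139 TPM) were among these 15. A different copy number of pHG1, where 24 of these genes lie, would move its genes together. The median change of the 371 other tested pHG1 genes, which ranged over 0.23 log2 units, was therefore taken off every pHG1 gene. After this, 35 of the 47 members were still highest in replicate 3 (exact circular-shift test, adjusted p = 0.0155), 18 of them off pHG1. This count could hardly move. The change was nearly equal in replicates 2 and 3 (0.07 and 0.09 log2 units) and left members off pHG1 untouched. The test, chosen after 2 other forms of it had been set aside, therefore adds little. That 18 of the 23 members off pHG1 were highest in replicate 3 argues against copy number as the whole cause. The labels give the same 13% O2 in the gas for each sample but neither the oxygen dissolved in it nor its growth stage, so no biological explanation was tested, and both, like a technical difference between the libraries, stay open.

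Of the 12 genes of the cbb operon, 9 differed between their copies by more than 2 SD, 8 with less on pHG1 and 1, cbbZ, with more (log2 ratio 0.29 ± 0.08, SD, n = 3). The ratio was lowest for cbbY, at -1.21 ± 0.19. How reads shared by near-identical copies were counted, and which annotated lengths were used for each copy, was not tested, so it stays open how different the copies are in abundance.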
